A study of Mus musculus with 14 samples.

How the data were processed

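Sin3A and Sin3B binding in C2C12 mouse myoblasts and myotubes was measured by chromatin immunoprecipitation and sequencing. Per the labels' protocols, chromatin was taken from sonicated nuclei and precipitated with antibody, and libraries were amplified by 18 cycles of PCR, selected at about 350 bp including adapters, and sequenced on the Illumina Genome Analyzer. The labels list 14 samples in 6 groups: 2 Sin3A and 2 Sin3B samples of myoblasts, 2 Sin3A and 5 Sin3B samples of myotubes, and 3 input samples, which were not analysed here. Per the labels, the antibodies against Sin3A and Sin3B share 1 catalogue number. The Sin3A myoblast samples used 2 antibody lots, the Sin3A myotube samples 1 of these, and the Sin3B samples 1 lot of their own.

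The authors deposited 11 peak lists as plain intervals of chromosome, start and end, with no header, score, height, p-value or gene name. The files of a group were byte-identical, which leaves 4 distinct lists with 7606 peaks in all. Each list was counted once, so n is 1 list per group. Whether it was called on pooled reads or on 1 sample and deposited repeatedly, and the aligner, caller, threshold, genome build and use of the input libraries, are not given in the sources used here. Depth is therefore unknown. PCR copies are not independent molecules, and intervals cover counting error only. Since every group has 1 list, tests with peaks as units describe these lists and cannot measure variation between cultures.

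The build was checked against a gene table of the GRCm38.p6 assembly. On 5 chromosomes peaks lay past the last gene of the table, and 10.6% of the 7606 peaks lay within 1 kb of a gene end, with over 50% on chromosome 16 alone (75.9%). The table was taken to be of another build, none of its coordinates were used for peaks, and no coordinates were converted. For this reason no peak was assigned to a gene, and the planned tests of promoters, of genes near peaks and of 22 gene lists fixed beforehand were not run. Motif and GC tests need a genome sequence of the files' build and the planned test of peak scores needs a score, so neither was run. The rule for naming items, fixed before the data were examined, took the 8 genes with the widest peak (where no score exists) in each class of each comparison. It was applied to merged regions in place of genes. Regions of 1 list were ordered by their widest peak, and regions common to 2 lists by the mean of the within-list ranks of their peak widths, so these do not follow the width of the single widest peak. The first 3 of the 8 are printed. Positions are written counting from 1, after adding 1 to the deposited starts.

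Overlap meant at least 1 bp, counted for peaks of the first list of a pair. Shares carry 95% Clopper-Pearson intervals. Random placement moved each peak anywhere on its chromosome within the span of the lists (1000 draws, two-sided), and local placement moved it by up to 50 kb. Regions were made by merging overlapping peaks of the lists compared, so numbers over 2 lists and over all 4 differ slightly. Shares were compared by Fisher's exact test, or by the exact McNemar test when the same peaks were set against 2 lists, two-sided, with Benjamini-Hochberg adjustment over 13 tests. Widths were compared by permutation of medians (100000 resamples, 8 tests). Peaks per chromosome were compared with 10000 random draws weighted by length, taken as the end of the last peak of any list (80 tests), and shares of chromosomes 15, 10 and X between lists by Fisher's exact test (12 tests, chosen after the folds were seen). The tests of regions that hold a protein at 1 stage only, the width tests and the exact McNemar tests were also chosen after the files were seen, in place of the gene and score tests. The threshold was an adjusted p of 0.05.

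Alternatives fixed beforehand were an overlap of 50% of the shorter peak, a distance of 1 kb, merging within 1 kb, and leaving out chromosome X. Others, chosen after seeing the data, were the wider peaks of each list, lists thinned to equal length, leaving out peaks under 50 bp, local placement, and weights by the number of protein-coding genes per chromosome in the GRCm38.p6 table without olfactory and vomeronasal receptor genes. On simulated lists of 759 peaks, overlap counting made an error of 0 peaks over 20 lists, and 0 of 40 randomly placed lists reached p below 0.05 in the permutation test. For the Sin3A myoblast list of 691 peaks, 91 of 100 planted 2-fold excesses on a chromosome were found, with 7 calls on the 19 unchanged chromosomes over the 100 simulations. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.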

Results

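Sin3A and Sin3B are related scaffold proteins of histone deacetylase complexes, which sequence-specific factors bring to chromatin. Their binding sites were mapped by chromatin immunoprecipitation and sequencing in C2C12 cells, a mouse skeletal muscle line that grows as single myoblasts and fuses into myotubes when serum is lowered. Growing myoblasts had been kept in 10% fetal bovine serum, and myotubes had been formed by confluent cells in 2% horse serum and parted from undifferentiated cells with diluted trypsin. There were 11 immunoprecipitation samples, namely 2 for Sin3A in myoblasts, 2 for Sin3A in myotubes, 2 for Sin3B in myoblasts and 5 for Sin3B in myotubes, and 3 input samples, whose signal was not analysed here. All files of a group were identical, so each group was represented by 1 peak list (n = 1) and no spread between replicates could be measured. Tests below therefore take peaks as units and compare the 4 lists, not the conditions. Read depth was unknown, and all intervals are 95% exact binomial (Clopper-Pearson) intervals that cover counting error only. The genome build of the peaks is not given in the sources used here and did not match the gene table at hand, so sites are named by position (counted from 1, in the files' own build) without genes. The labels give 1 catalogue number for the antibodies against both proteins, which bears on every comparison between them.

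Sin3B had many more peaks than Sin3A at both stages. The Sin3A lists held 691 peaks in myoblasts and 759 in myotubes, and the Sin3B lists held 2387 and 3769. Sin3B peaks outnumbered Sin3A peaks 3.45-fold in myoblasts and 4.97-fold in myotubes. From myoblasts to myotubes the number rose 1.10-fold for Sin3A and 1.58-fold for Sin3B, and myotubes held 52.3% (49.7 to 54.9%) of the Sin3A peaks of both stages and 61.2% (60.0 to 62.4%) of the Sin3B peaks (Fisher's exact test, two-sided, adjusted p = 1.04e-09). The peaks covered 282 kb for Sin3A in myoblasts, 374 kb for Sin3A in myotubes, 1275 kb for Sin3B in myoblasts and 2233 kb for Sin3B in myotubes. With no reads or peak scores at hand, a change in list length could not be separated from a change in depth or threshold.

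Peaks were narrow, with median widths of 410 bp for Sin3A in myoblasts, 474 bp for Sin3A in myotubes, 498 bp for Sin3B in myoblasts and 545 bp for Sin3B in myotubes. Myotube peaks were wider than myoblast peaks for both proteins, and Sin3B peaks were wider than Sin3A peaks at both stages (permutation tests of the medians, two-sided, all 4 at p = 2.00e-05, the smallest value that the resampling can give, adjusted p = 2.29e-05). As with list length, a difference in width between lists could not be separated from a difference in depth or threshold. Within each list, peaks that overlapped another list were wider than those that did not. The medians were 429.5 and 386 bp for Sin3A in myoblasts, 486 and 407 bp for Sin3A in myotubes, 539 and 442.5 bp for Sin3B in myoblasts, and 616 and 494 bp for Sin3B in myotubes (permutation tests, adjusted p = 4.80e-04 for the first and 2.29e-05 for the others).

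**Figure D1:**
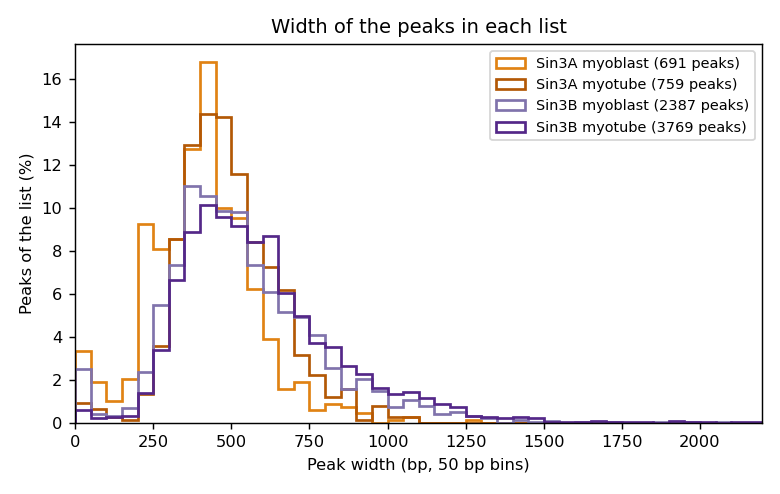
Share of the peaks of each list (percent, vertical axis) by peak width in 50 bp bins (bp, horizontal axis), 1 line per list. The median moves from 410 bp in the Sin3A myoblast list to 545 bp in the Sin3B myotube list, and 3.33% of the Sin3A myoblast peaks are shorter than 50 bp.

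The first comparison asks how Sin3A binding changed as myoblasts became myotubes. Few Sin3A sites were common to both stages. Of the 691 myoblast peaks, 130 (18.8%, 16 to 21.9%) overlapped a myotube peak by at least 1 bp, and 131 of the 759 myotube peaks (17.3%, 14.6 to 20.1%) overlapped a myoblast peak. Merged over both stages, Sin3A occupied 1316 regions, of which 561 (42.6%, 39.9 to 45.4%) had a peak in myoblasts only, 628 (47.7%, 45.0 to 50.5%) in myotubes only and 127 (9.65%, 8.11 to 11.4%) at both stages. The overlap was 660 times the mean of 0.197 peaks found when peaks were placed at random on their chromosomes, and 63.4 times the mean after moving each peak by up to 50 kb. Random placement never gave more than 3 overlapping peaks in 1000 draws (permutation p = 0.002, the smallest value the draws can give, here and for all 12 ordered pairs of lists). Centres of overlapping peaks lay a median of 101.5 bp apart. Neither placement keeps peaks to promoters or open chromatin. Folds over them, here and for all pairs of lists, thus cannot show overlap beyond a shared preference for such regions.

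The widest Sin3A peaks found in myoblasts only were on chromosome 12 at 74146285 to 74147349, and on chromosome 15 at 38229889 to 38230941 and at 34372860 to 34373801. Each of these 3 regions also held a Sin3B peak in myoblasts. Regions with Sin3A at both stages were ordered by the mean width rank of their peaks in the 2 lists, as were all regions common to a pair of lists. The first 3 were on chromosome 5 at 93696114 to 93697476, on chromosome 17 at 46167075 to 46168431, and on chromosome 15 at 57966093 to 57967178, and all 3 held Sin3B in myotubes. In myotubes only, the widest Sin3A peaks were on chromosome 1 at 181732684 to 181733732, on chromosome 15 at 99802875 to 99803877, and on chromosome 12 at 11272224 to 11273213, again each with a Sin3B myotube peak. The 8 regions ranked first in each class all had a Sin3B peak at some stage, but the whole classes differed. A Sin3B peak at either stage was found at 209 of 554 regions with Sin3A in myoblasts only (37.7%, 33.7 to 41.9%), at 510 of 621 with Sin3A in myotubes only (82.1%, 78.9 to 85.1%) and at 120 of 129 with Sin3A at both stages (93.0%, 87.2 to 96.8%), counted over regions merged from all 4 lists.

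The same comparison for Sin3B gave a different balance. In the full lists, most Sin3B sites of myoblasts were also listed in myotubes, and the myotube list added a larger set. Of the 2387 myoblast peaks, 1437 (60.2%, 58.2 to 62.2%) overlapped a myotube peak. This share depended on list length, and was 45.0% with the 2387 widest myotube peaks and 38.4% with the myotube list thinned at random to 2387. In the other direction, 1434 of the 3769 myotube peaks (38.0%, 36.5 to 39.6%) overlapped a myoblast peak. Of 4689 merged Sin3B regions, 950 (20.3%, 19.1 to 21.4%) had a peak in myoblasts only, 1404 (29.9%, 28.6 to 31.3%) at both stages and 2335 (49.8%, 48.4 to 51.2%) in myotubes only. The overlap was 314 times that of random placement and 38.5 times that of local shifts.

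Myoblast-only Sin3B regions with the widest peaks lay on chromosome 15 at 61817115 to 61819177, on chromosome 18 at 75529438 to 75531288, and on chromosome 6 at 31035007 to 31036533, and each held a Sin3A myoblast peak. The other 5 of the 8 widest held no Sin3A peak, and over the whole class 46 of 943 regions (4.88%) held Sin3A in myoblasts. Regions with Sin3B at both stages were led, by mean width rank, by those on chromosome 5 at 31481067 to 31483017, with Sin3A in myotubes, on chromosome 10 at 17442652 to 17444569, with Sin3A in myoblasts, and on chromosome 12 at 111828993 to 111830677, with no Sin3A peak. Myotube-only Sin3B regions with the widest peaks were on chromosome 17 at 29627684 to 29629785 and on chromosome 1 at 59538925 to 59540916, both without a Sin3A peak, and on chromosome 17 at 45709240 to 45711042, with Sin3A in myotubes.

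Set side by side, a smaller share of Sin3A than of Sin3B myoblast peaks was listed again in myotubes (18.8% against 60.2%, Fisher's exact test, two-sided, adjusted p = 3.11e-85), and a smaller share of Sin3A than of Sin3B myotube peaks was already listed in myoblasts (17.3% against 38.0%, Fisher's exact test, adjusted p = 3.96e-30). These shares grow with the length of the lists compared. When the Sin3B lists were thinned at random to the lengths of the Sin3A lists, the share of Sin3B myoblast peaks listed again averaged 12.3% (range 8.25 to 16.4% over 1000 draws) and the difference turned its direction, as thinning scales a share by about the fraction of peaks kept in the list that is met. With the widest Sin3B peaks in the same numbers it was 33.0% (29.5 to 36.6%), above that of Sin3A, so the direction was kept. This cut was made in the Sin3B lists only, where peaks shared with another list were wider, so it favours the Sin3B share. Neither way of evening out list length settles the comparison.

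In myoblasts, most peaks of each protein did not overlap a peak of the other. With depth and threshold unknown, a missing peak does not show that the protein was absent. Of the Sin3A myoblast peaks, 229 (33.1%, 29.6 to 36.8%) overlapped a Sin3B myoblast peak, and of the Sin3B myoblast peaks, 232 (9.72%, 8.56 to 11%) overlapped a Sin3A peak. Of 2843 merged regions, 462 (16.3%, 14.9 to 17.7%) held Sin3A only, 226 (7.95%, 6.98 to 9.01%) held both proteins and 2155 (75.8%, 74.2 to 77.4%) held Sin3B only. The overlap was 302 times that of random placement and 44.1 times that of local shifts. Widest among the regions with Sin3A only were those on chromosome 10 at 84038952 to 84040213, on chromosome 15 at 66800353 to 66801252, and on chromosome 19 at 5842920 to 5843808. Those on chromosomes 10 and 19 held a Sin3B peak in myotubes. Of the 8 ranked first in this class, 7 had a peak in a myotube list. By mean width rank, the regions with both proteins were led by those on chromosome 12 at 74145064 to 74147349, on chromosome 10 at 17442904 to 17444394, and on chromosome 8 at 87501911 to 87502904. Sin3B-only regions were led by those on chromosome 5 at 31481067 to 31483017, on chromosome 17 at 25152074 to 25153818, and on chromosome 8 at 87185203 to 87186810, all of which also held a Sin3B peak in myotubes. Those on chromosomes 5 and 8 held a Sin3A peak in myotubes too.

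In myotubes, most Sin3A sites were also Sin3B sites. Of the Sin3A myotube peaks, 616 (81.2%, 78.2 to 83.9%) overlapped a Sin3B myotube peak, with a median of 90 bp between centres, and 619 of the Sin3B myotube peaks (16.4%, 15.3 to 17.6%) overlapped a Sin3A peak. Of 3903 merged regions, 143 (3.66%, 3.10 to 4.30%) held Sin3A only, 610 (15.6%, 14.5 to 16.8%) held both and 3150 (80.7%, 79.4 to 81.9%) held Sin3B only. The overlap was 429 times that of random placement and 45.5 times that of local shifts, neither of which allows for regions that both lists may favour. By mean width rank, the regions with both proteins were led by those on chromosome 16 at 8830133 to 8831536, on chromosome 15 at 76307159 to 76308459, and on chromosome 5 at 93696079 to 93697328. Regions with Sin3A only were led by those on chromosome 8 at 88364342 to 88365204, on chromosome 10 at 86167301 to 86168160, and on chromosome 8 at 97855175 to 97856003. Both regions on chromosome 8 held a Sin3B peak in myoblasts. Sin3B-only regions were led by those on chromosome 12 at 88223470 to 88225626, on chromosome 17 at 29627684 to 29629785, and on chromosome 15 at 76034923 to 76036922. Those on chromosomes 12 and 15 held both a Sin3A and a Sin3B peak in myoblasts.

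**Figure D2:**
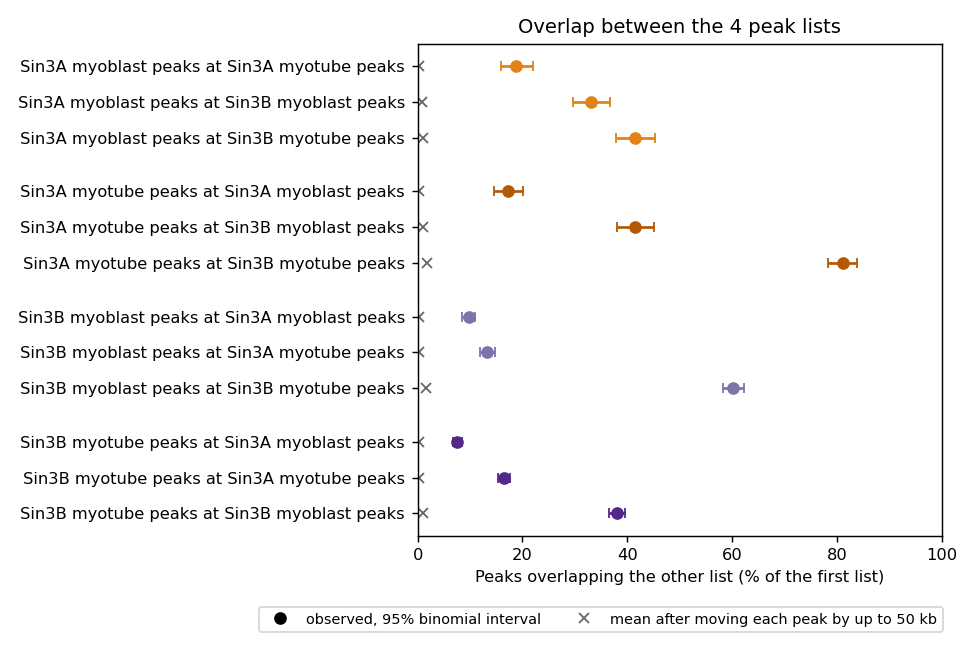
Percent of the peaks of each list (horizontal axis) that overlap another list by at least 1 bp, for the 12 ordered pairs, as points with 95% exact binomial intervals and crosses for the mean after moving each peak by up to 50 kb. Every point lies far above its cross, and the highest share is 81.2%, of Sin3A myotube peaks at Sin3B myotube peaks.

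The share of Sin3A peaks at Sin3B peaks of the same stage was thus 48.0 percentage points higher in myotubes than in myoblasts (81.2% against 33.1%, Fisher's exact test, two-sided, adjusted p = 9.68e-79). The share of Sin3B peaks at Sin3A peaks was also higher in myotubes (16.4% against 9.72%, Fisher's exact test, adjusted p = 7.86e-14). With the Sin3B myotube list thinned at random to the length of the myoblast list, the Sin3A myotube share averaged 51.6% (range 47.6 to 55.9%), a difference of 18.5 points (Fisher's exact test, p = 1.36e-12).

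Regions listed with 1 protein at 1 stage only were then compared for peaks of the other protein, over the 5137 regions merged from all 4 lists. These counts largely rest on the same overlaps as the shares above and are no separate support for them. A peak in only 1 of 2 lists of unknown depth does not by itself show a change of binding. Regions with Sin3A in myotubes only carried Sin3B in myotubes in 493 of 621 cases (79.4%, 76.0 to 82.5%), and regions with Sin3A in myoblasts only in 165 of 554 cases (29.8%, 26.0 to 33.8%; Fisher's exact test, two-sided, adjusted p = 1.71e-67). The same classes carried Sin3B in myoblasts in 237 (38.2%) and 145 (26.2%) cases (Fisher's exact test, adjusted p = 1.46e-05). Of the 129 regions with Sin3A at both stages, 118 (91.5%, 85.3 to 95.7%) held Sin3B in myotubes and 86 (66.7%, 57.8 to 74.7%) held it in myoblasts. Regions with Sin3B in myotubes only held Sin3A in myotubes in 307 of 2324 cases (13.2%, 11.9 to 14.7%), against 19 of 943 (2.01%, 1.22 to 3.13%) for those with Sin3B in myoblasts only (Fisher's exact test, adjusted p = 1.92e-27). For Sin3A in myoblasts no difference between these Sin3B classes was detected, at 98 (4.22%, 3.44 to 5.12%) and 46 regions (4.88%, 3.59 to 6.45%; Fisher's exact test, adjusted p = 0.399).

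Across all lists, 3289 of the 5137 regions (64.0%) had a peak in 1 list and 84 had one in all 4. The most frequent patterns were Sin3B in myotubes only (1953 regions), Sin3B at both stages without Sin3A (1000) and Sin3B in myoblasts only (880). Sin3A in myoblasts alone accounted for 345 regions and Sin3A in myotubes alone for 111. The share of peaks found in no other list was 49.9% (46.1 to 53.7%) for Sin3A in myoblasts, 14.6% (12.2 to 17.3%) for Sin3A in myotubes, 36.9% (34.9 to 38.8%) for Sin3B in myoblasts and 51.8% (50.2 to 53.4%) for Sin3B in myotubes.

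**Figure D3:**
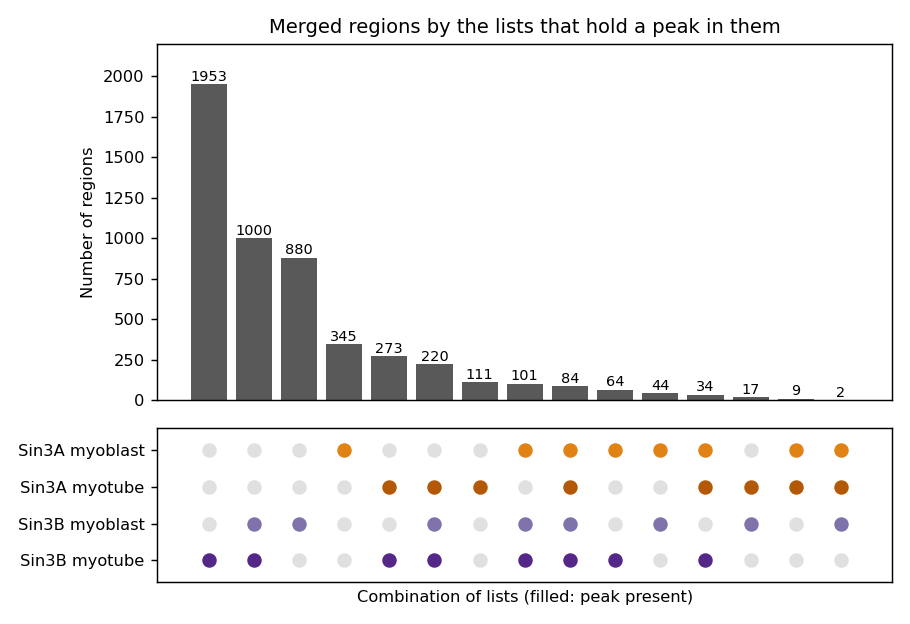
Number of merged regions (vertical axis of the bars) for each of the combinations of lists with a peak in them, which the filled dots under each bar mark. The tallest bar, 1953 regions, is Sin3B in myotubes alone, and 84 regions have a peak in all 4 lists.

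Peaks were unevenly spread over the 20 chromosomes. Relative to length, 5 to 8 chromosomes per list were called above and 4 to 8 below, and only some are described here. Calls came from a random-draw test, in which peaks are drawn over chromosomes with weights by length. The number of copies of each chromosome in these cells was not analysed here, and every fold by chromosome is relative to length alone unless stated. Chromosome 11 held about 2-fold more peaks than its length gives in every list, with folds of 2.19 for Sin3A and 2.09 for Sin3B in myoblasts and of 2.16 for Sin3A and 2.11 for Sin3B in myotubes (permutation of peaks over chromosomes, two-sided, adjusted p = 4.71e-04 over 80 tests). Weighted by gene number in place of length, these folds were lower, at 1.34, 1.28, 1.32 and 1.29 in the same order. Chromosome X was low in all 4, with 6 and 7 Sin3A peaks in myoblasts and myotubes (folds of 0.137 and 0.146) and 25 and 27 Sin3B peaks (folds of 0.165 and 0.113; permutation, adjusted p = 4.71e-04). Chromosome 7 was also low in all 4 (random-draw test, adjusted p of 0.0133 or less). Its folds were 0.474 and 0.591 for Sin3A and 0.607 and 0.755 for Sin3B, in myoblasts and myotubes. Weighted by gene number, they were 0.344 to 0.547. Chromosome 19 was high in all 4 (permutation, adjusted p of 0.00575 or less). Its folds were 1.86 and 1.75 for Sin3A and 1.63 and 1.73 for Sin3B, and 1.20 to 1.36 weighted by gene number. With these weights the same permutation detected an excess for Sin3B in myotubes only. In the other lists the excess of chromosome 19 was thus not detected beyond its gene number. Chromosome 15 was above its length in each list. The fold was 2.80 for Sin3A in myoblasts, 1.98 for Sin3A in myotubes, 1.70 for Sin3B in myoblasts and 1.5 for Sin3B in myotubes (permutation, adjusted p = 4.71e-04). Chromosome 10 was above its length for Sin3A at both stages (1.80 and 1.78, permutation, adjusted p = 7.62e-04) and for Sin3B in myotubes (1.3, adjusted p = 0.00109), and no excess was detected for Sin3B in myoblasts (1.11, adjusted p = 0.268). The raw p of 1.00e-04 behind the values of 4.71e-04 is the smallest that the draws of this test can give. The draws treat peaks as independent, but some lay close together, with 267 neighbours under 1 kb apart in the Sin3B myotube list. The p-values by chromosome may therefore be too small.

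Between lists, chromosome 15 took 11% of the Sin3A and 6.70% of the Sin3B peaks in myoblasts (Fisher's exact test, two-sided, adjusted p = 0.00398 over 12 tests). The Sin3A share of 7.77% in myotubes was not distinguishable from either the Sin3A myoblast share (exact test, adjusted p = 0.112) or the Sin3B myotube share of 5.89% (exact test, adjusted p = 0.138). Chromosome 10 took 8.83% of the Sin3A and 5.45% of the Sin3B peaks in myoblasts (exact test, adjusted p = 0.0101), and 8.70% and 6.37% in myotubes (exact test, adjusted p = 0.105). Shares of chromosome X did not differ detectably between lists (exact tests, adjusted p from 0.319 upward).

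**Figure D4:**
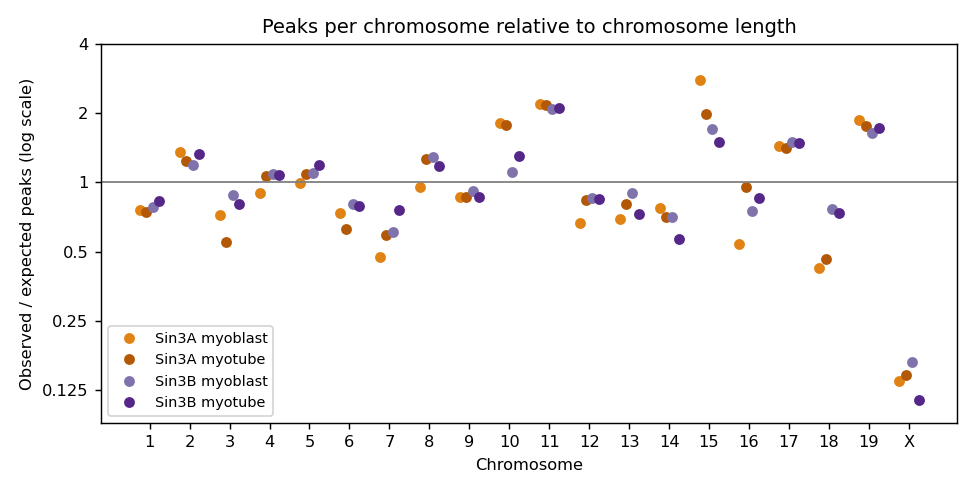
Observed over expected number of peaks per chromosome, with expectation by length, on a log axis, 1 point per list. Chromosome 11 lies near 2 in all 4 lists, chromosome 15 runs from 1.5 to 2.80, and chromosome X lies between 0.113 and 0.165.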

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

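Of the tests in this part, those of the shared antibody product, of background regions, of gene number and of chromosome copies were chosen only after the results were seen, and the thinned and widest lists were chosen after seeing the data. Differences between groups singled out 3 results. The share of Sin3A minus Sin3B myoblast peaks listed again in myotubes was -41.4 percentage points. It kept its direction with the widest Sin3B peaks in the numbers of the Sin3A lists (-14.2 points) and changed it with Sin3B lists thinned at random (6.48 points), which lowers the Sin3B share by construction. The cut to the widest peaks favours the Sin3B share, since shared peaks were wider and the Sin3A lists were kept whole. The myotube share of the peaks of both stages, Sin3A minus Sin3B, was -8.88 points. The share of Sin3A peaks at Sin3B peaks, myotubes minus myoblasts, was 48.0 points.

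Sin3A sites coincided with Sin3B sites far more often in myotubes (81.2%) than in myoblasts (33.1%). The number of Sin3B myotube peaks alone is not the whole cause, since the lowest share over 1000 lists thinned to the myoblast length was 47.6%, above the upper bound of 36.8% in myoblasts. Such thinning only scales the share by about the fraction of peaks kept. It does not cover differences in depth or threshold between the lists, or noise in the Sin3A myoblast list. Background regions found only in myotube libraries are not the whole cause either, since 55.3% of the regions with both proteins in myotubes also had a peak in myoblasts. Precipitation of both proteins by the same antibody product cannot be told apart from shared sites: it would put most Sin3A peaks at Sin3B peaks at both stages, and the 33.1% in myoblasts goes against that only if the Sin3A myoblast list holds little noise, which is not known. A change of Sin3 binding with differentiation stays open as a hypothesis and was not tested, since stage and list are the same split here.

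Chromosome 15 held 2.80-fold more Sin3A myoblast peaks than its length gives. Gene number does not account for it, as the fold weighted by gene number was 2.89. A single cluster does not account for all of it, since the density relative to all other chromosomes was 3.02 with and 2.46 without the densest 5 Mb. Extra copies of the whole chromosome in the cell line could raise the peaks of both proteins and stay open: the Sin3B myoblast list was raised too, 1.70-fold, but less, with an odds ratio of 1.72 (1.27 to 2.31) for Sin3A against Sin3B in myoblasts, and how strongly copies act on lists of such different length is not known. The input libraries, not analysed here, would bear on this, and no biological explanation was tested.

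Sin3A myoblast peaks found in no other list made up 49.9% of that list. Chance placement of false peaks along the chromosomes is not the whole cause, since 2.9% of them (interval 0 to 19.8%) were spread as length gives when the rest followed the Sin3B myotube list. False peaks that follow copy number or open chromatin are not covered by that test. Narrow peaks could account for part: among the 173 widest peaks, 32.9% (26.0 to 40.5%) were found in no other list, between the bounds set for and against this explanation. Binding particular to Sin3A in myoblasts stays open and was not tested. The antibody lot used for Sin3A in myoblasts only was not tested as a cause either.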

How the results depend on the processing

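Over 40 results and 96 alternative values, 72 were counted as unchanged, 23 as moved and 1 as reversed. Unchanged meant that shares stayed within their interval, and that tested differences and folds kept their direction and side of the threshold. Counts of peaks and of regions were all counted as unchanged, which does not mean that they stayed within an interval. With a distance of 1 kb, Sin3B regions went from 950 to 791 in myoblasts only. They went from 1404 to 1466 at both stages and from 2335 to 2031 in myotubes only. Lists of peaks wider than the median, thinned and widest lists, the 50 bp limit and gene number were chosen after seeing the data. Values are given in this order for Sin3B myoblast peaks at Sin3B myotube peaks (60.2%), Sin3A at Sin3B in myoblasts (33.1%), Sin3A at Sin3B in myotubes (81.2%), Sin3A myoblast at Sin3B myotube peaks (41.5%) and Sin3A myotube at Sin3B myoblast peaks (41.5%). An overlap of 50% of the shorter peak gave 55.9, 29.1, 77.9, 37.8 and 37.8%, and a distance of 1 kb moved Sin3B across stages, Sin3A at Sin3B in myotubes and the last to 65.2, 84.6 and 45.5%. Peaks wider than their list's median gave 49.5, 18.8, 67.5, 37.4 and 30.6%. The longer list thinned at random to the shorter gave 38.4, 9.73, 16.6, 7.76 and 13.4%, and its widest peaks in the same number gave 45.0, 10.4, 30.8, 14.8 and 17.7%, both lower by construction since fewer peaks can be met. Sin3A myoblast peaks at Sin3A myotube peaks stayed at 16.5 to 20.3% throughout. The retention difference, Sin3A minus Sin3B, of -41.4 points reversed to 6.48 with Sin3B lists thinned at random, which removes shared peaks by construction, and was -14.2 with the widest Sin3B peaks and -32.6 to -44.9 otherwise. Taking the widest peaks of the Sin3B lists only favours shared peaks, which were wider. The stage difference of 48.0 points ranged from 18.5 to 49.3. No paired analysis was possible because the files of each group were identical, which leaves 1 list per group, and leaving out replicates was impossible for the same reason. Alternatives listed beforehand on scores, promoter widths, gene windows and control sequences were not run, for want of scores and of a matching genome. Unknown depth limits every comparison of list length.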

Other observations

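Overlap also crossed stages. Of the Sin3A myoblast peaks, 41.5% (37.8 to 45.3%) lay at Sin3B myotube peaks, more than the 33.1% at Sin3B peaks of their own stage (exact McNemar test, two-sided, adjusted p = 5.94e-06). Of the Sin3A myotube peaks, 41.5% (38.0 to 45.1%) lay at Sin3B myoblast peaks, against 81.2% at Sin3B myotube peaks (exact McNemar test, adjusted p = 3.96e-69). Sin3B myoblast peaks met Sin3A myotube peaks in 13.3% and Sin3A myoblast peaks in 9.72% of cases (exact McNemar test, adjusted p = 2.18e-05), and Sin3B myotube peaks in 16.4% and 7.59% (exact McNemar test, adjusted p = 6.21e-39). In each of these 4 comparisons the myotube list, which was the longer of its pair, was met more often. The order for the Sin3A myoblast peaks depended on how list length was evened out. With the 691 widest peaks of each Sin3B list, 14.8% lay at Sin3B myotube and 10.4% at Sin3B myoblast peaks, the same order as in the full lists. Random thinning to 691 peaks gave 7.76% (range 5.07 to 11.1%) and 9.73% (range 6.95 to 12.6%), but it scales each share by about the fraction of peaks kept, so the longer myotube list loses more by construction, and the ranges overlap. The widest and thinned lists and the McNemar tests were chosen after seeing the data.

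The stretch of 5 Mb with the most peaks was the same in all 4 lists, on chromosome 15 from 75 to 80 Mb, with 17 and 15 Sin3A peaks in myoblasts and myotubes and 41 and 55 Sin3B peaks. The next densest stretches were on chromosome 4 from 115 to 120 Mb for Sin3A in myotubes (12 peaks), on chromosome 8 from 85 to 90 Mb for Sin3B in myoblasts (30 peaks) and on chromosome 19 from 5 to 10 Mb for Sin3B in myotubes (47 peaks).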
